A study of Mus musculus with 30 samples.

How the data were processed

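Single-cell libraries of live CD45+ cells from CT26 tumours of female BALB/c mice were analysed, 30 libraries with 1 tumour each. The labels carry no mouse number, and each library was taken as a separate mouse. Reads were aligned to mm10 and UMIs counted with Cell Ranger 2.1.1, per the submitters' processing notes. The deposited matrices hold a UMI count per gene and barcode, for 28692 genes and 146949 barcodes. The deposited annotation gives a class for 143680 cells in 28 classes and a myeloid table of 81370 cells in 15 classes, with the same class in both for all of them. It also gives the mitochondrial share of each cell, a fraction from 0 to 1 per the file headers despite a column name that speaks of percent. The total count of every annotated cell in the authors' table equalled its matrix total. Annotated cells had at least 2224 UMIs, at most 4999 genes and at most 10.0% mitochondrial UMIs. How the authors set these limits and whether doublets were removed is not given in the sources used here. The post-treatment tumour size is given without a unit per the labels, for 26 libraries.

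Counts were summed per library and class, since cells of the same mouse are not replicates. CPM was computed here from the summed counts and their total. The 125 genes that share a symbol with another gene were kept apart by ID. Monocytes and macrophages are classes M_1 to M_9. The rule written before the data were examined took classes with Mac, TAM or Mono in the name, which matched only M_5_Mono, so the set was widened after the class names and marker genes were seen. M_10 was left out for its neutrophil genes (S100a8, S100a9). M_9, 420 cells of mixed markers, stayed in. No class is named for Cxcl9, and M_3 was taken for its Cxcl9 level. The background was read in T and NK cells, because the B cell class has only 86 cells.

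Relations with log2 size used Spearman's rho and Pearson's r of the logit share, with 0.5 cells added to both sides, and two-sided p values from 100000 permutations, with all 720 orders for sets of 6 libraries. Adjusted p values are Benjamini-Hochberg values over the classes of a table. Cells were thinned to 1000 UMIs (2000 as an alternative) before the share with a Cxcl9 UMI was taken. Genes were tested with the edgeR quasi-likelihood test (filterByExpr, TMM factors) of the slope on log2 size, or on log2 Cxcl9 CPM of the macrophages, in libraries with 20 or more cells of the class and classes with 15 or more such libraries. B_1, CD45neg2, DC_5_pDC, M_9 and M_10 had fewer and were not analysed here for genes. Gene lists, 17 in number and written before the data were examined, were tested with limma camera at a preset correlation of 0.01, again with the estimated correlation, and with fry, whose p asks whether the members move at all and not whether they move more than other genes. The preset correlation gives p values that are too small where members vary together, and the estimated correlation was 0.832 for the interferon-γ list in macrophages. The tests of macrophages, T cells, all CD45+ cells, M_2, M_4, the library sets and the relation with Cxcl9 were repeated with values assigned to libraries at random 99 times. For the relation with Cxcl9, macrophage RNA was also subtracted from the T and NK counts of each library, in proportion to the macrophage profile of the library and scaled by C1qa, C1qb, C1qc and Apoe or by Cxcl9. These were at a median of 2.07% and 2.60% of their macrophage level. This was added after the data were seen.

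Named genes follow a rule written before the data were examined. For macrophages, all CD45+ cells and the relation with Cxcl9 these are up to 10 genes per direction with the lowest adjusted p under 0.05 and a mean of 10 CPM or more, or 3 per direction where none pass. For each other class they are up to 3 per direction, and for each list 2 to 4 members with the lowest p. Cxcl9, Cxcl10, Cd274, Nos2, Arg1, Spp1, Mrc1, C1qa, H2-Ab1 and Ly6c2 in macrophages and Ifng, Gzmb, Prf1, Pdcd1, Cd8a and Foxp3 in T cells are always given. Positions are those of GENCODE M21.

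The comparisons and tests were fixed at the same time, and so were these alternatives: DESeq2, no filter on low counts, RLE factors, untransformed size, a split at the median size, depth as a covariate, libraries under 2000 annotated cells left out, possible doublets left out (cells with both Cd3 and C1q UMIs, 8271 or 5.76% of annotated cells), and each library left out in turn. The division into libraries 1 to 22 and 23 to 30 came from a scan over library numbers after the data were seen, as did all alternatives that use it. The tests were tested on simulated data without correlation between genes. For the gene tests, slopes were planted in many genes at once, all of 10 CPM or more, which eases the adjusted threshold. The recovered shares therefore do not say how often a lone slope, or that of a gene with less RNA, would pass. In macrophages, 89.6% of planted slopes of 0.15 and 98.5% of those of 0.30 were recovered, with 9 false calls among 12504 unchanged genes. For the relation with Cxcl9 the recovered shares were 25.4% and 92.5%. The correlation test gave p under 0.05 in 5.30% of 2000 measures with no relation and in 98.7% with a planted correlation of 0.70.

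Depth ran from 11324913 annotated UMIs in library 4 to 66321686 in library 6, and median genes per cell from 1980 to 2852. The precision of each value is given as an SD or SE over libraries. The 3269 barcodes without a class were not used in the comparisons. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.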

Results

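The series profiled immune cells of CT26 tumours, which grow from a mouse colon carcinoma cell line, before treatment with avelumab, an antibody against PD-L1. Each female BALB/c mouse carried a tumour on both flanks. A tumour of each pair was taken out on day 8. Its live cells with CD45, the surface protein of white blood cells, were sorted and sequenced as single cells with the 10x kit, which tags each RNA molecule in a droplet with a unique identifier (UMI). The size of the tumour left in place, measured after treatment, is the only response given, and its unit is not stated in the labels. There are 30 libraries, read as 1 per mouse and all of 1 group, and 26 of them carry a size, from 23 to 1582 with a median of 365. Libraries 4, 22, 23 and 24 have no size and entered only the comparisons that need none. The matrices hold 146949 barcodes, of which the authors annotated 143680 cells in 28 classes, 15 of them myeloid with 81370 cells. UMI totals ran from 13104315 in library 4 to 73576019 in library 1, annotated cells from 1248 in library 4 to 6755 in library 7, and median UMIs per annotated cell from 5856 to 11160. No library repeats another: over 13747 genes and 435 pairs, the lowest chi-square per degree of freedom was 20.2 and the median 90.3.

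Cxcl9 RNA was most abundant in macrophage class M_3. The gene encodes an interferon-induced chemokine that attracts T and NK cells through the receptor Cxcr3 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079, minus strand, mm10). M_3 held 2599 ± 549 CPM (SD, n = 30), followed by M_8 with 905.1 ± 451 CPM (n = 29). The monocyte class M_5_Mono had 741 ± 557 CPM and the macrophage class M_6, which was richest in Arg1 (5181 ± 1282 CPM), had 88.0 ± 85.1 CPM of Cxcl9. M_3 also carried 1003 ± 200.3 CPM of Cxcl10, another ligand of Cxcr3, 266 ± 72.0 CPM of Cd274, which encodes PD-L1, and 78.5 ± 82.8 CPM of Nos2, the inducible nitric oxide synthase. Its H2-Ab1 level, an MHC class II gene, was 7046 ± 1094 CPM. Cxcl9 was 89.5 ± 93.0 CPM in the regulatory T cell class T_2_Treg. No class is named for Cxcl9 in the annotation, so M_3 stands for the Cxcl9 macrophages throughout, and these levels describe classes without a test.

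**Figure D1:**
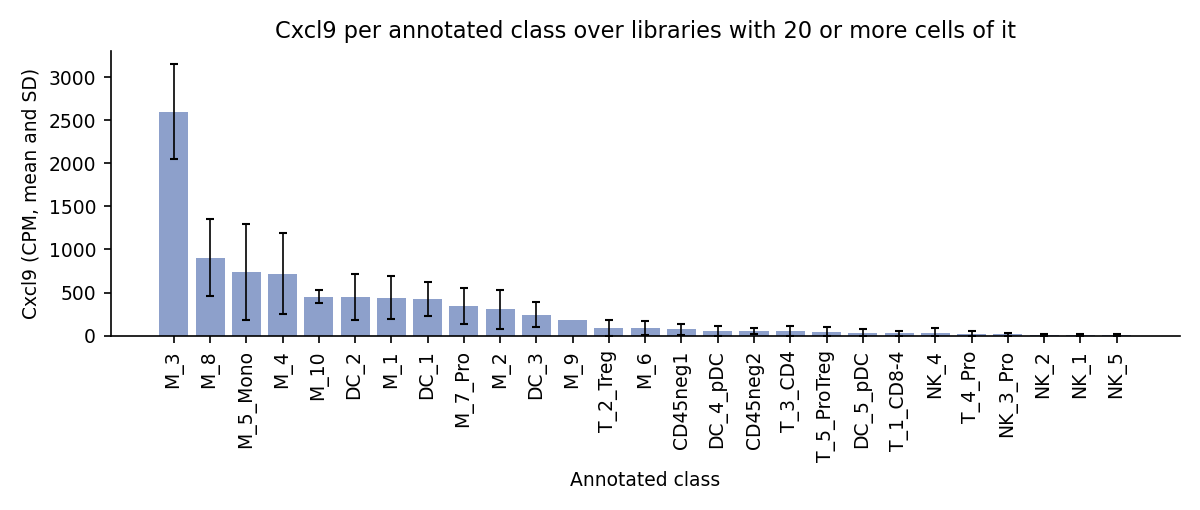
Cxcl9 level of each annotated class (y axis, CPM of the counts summed per library and class; bars are means and error bars SDs over libraries with 20 or more cells of the class, with no SD for M_9, which has 1 such library). M_3 stands at 2599 CPM, above M_8 at 905.1 CPM.

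Many genes differed between libraries with low and high numbers. A scan over the split positions with at least 4 libraries on each side, made after the data were seen, found the most differing genes between libraries 1 to 22 and libraries 23 to 30. In all CD45+ cells, 884 genes were higher and 715 lower in libraries 23 to 30 out of 14298 tested (edgeR quasi-likelihood test, adjusted p under 0.05). Among the genes higher there were Sqstm1, an autophagy adaptor, by 0.70 ± 0.09 log2 (SE, adjusted p = 4.6e-06), Srxn1, which repairs oxidised peroxiredoxins, by 0.77 ± 0.10 (adjusted p = 2.5e-05), and the chaperone gene Hsp90aa1 by 0.91 ± 0.21 (adjusted p = 0.00535), all by edgeR. Among the lower ones were the immediate early genes Fos (-0.68 ± 0.15, adjusted p = 0.00382) and Nr4a1 (-0.60 ± 0.10, adjusted p = 0.000296) in the same edgeR fit. Others of these kinds did not pass or went the other way: Jun had -0.10 ± 0.17 (edgeR adjusted p = 0.748), Atf3 -0.33 ± 0.17 (adjusted p = 0.214), Hspa1b 1.35 ± 0.54 (adjusted p = 0.0954) and Dnajb1 0.49 ± 0.23 (adjusted p = 0.156), and Gadd45b was higher by 0.27 ± 0.08 (adjusted p = 0.0286). The genes of this paragraph were chosen after their values were seen. The list of dissociation and stress genes did not shift as a whole (camera adjusted p = 0.851, p = 0.95002 with the estimated correlation), with 11 members called higher and 9 lower of 29. The ribosomal list was higher (camera adjusted p = 3.1e-08, p = 0.0506 with the estimated correlation) and the monocyte list lower (camera adjusted p = 0.0349, p = 0.174 with the estimated correlation). They were among 7 lists called, and 65 of 100 splits, the real one included, called as many. Taken singly, both shifts (mean signed root F of members minus that of other genes) went farther than in every random split. The ribosomal list stood at 2.68 (highest other 1.71) and the monocyte list at -1.25 (highest other 1.19 in either direction). Each had a share of 1 of 100 and an adjusted share of 0.085, and the split itself was picked by a scan. The other tumours of these mice were also larger: the 6 sized libraries from 23 to 30 had a median size of 898.5 (356 to 1582) against 285 (23 to 819) in the 20 sized libraries from 1 to 22, a log2 difference of 1.65 (permutation p = 0.0167, two-sided). The labels name no batch. The split therefore overlaps with size in part, and the relations of M_3, of T_5_ProTreg and of macrophage Cxcl9 with size are given pooled, in each set, and by ranks within the sets.

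**Figure D2:**
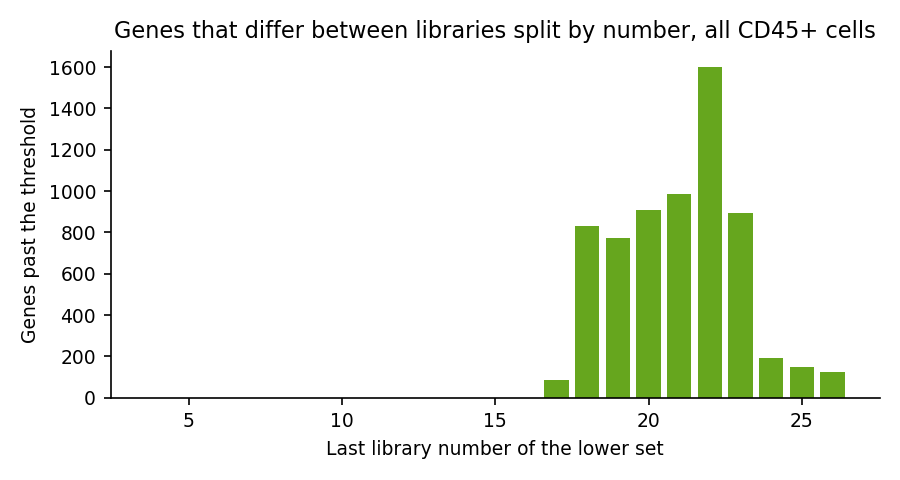
Genes that differ in all CD45+ cells (y axis, genes with adjusted p under 0.05 by edgeR) when the libraries are split by number, against the last library number of the lower set (x axis). The highest bar, 1599 genes, stands at library 22.

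Across mice, the share of regulatory T cells in division was higher where the other tumour ended up larger, and the share of the Cxcl9-rich macrophages was lower. T_5_ProTreg, which carried 420 ± 78.5 CPM of Foxp3, the lineage factor of regulatory T cells, made up 1.07% ± 0.43 of CD45+ cells (SD, n = 26) and rose with size (Spearman rho = 0.65, permutation p = 0.00042, adjusted p = 0.0118 over 28 classes). Its Pearson r with log2 size was 0.71 (permutation p = 4.0e-05). M_3 made up 6.07% ± 2.61 of CD45+ cells and fell with size (rho = -0.57, permutation p = 0.00272, adjusted p = 0.0381). Its r of -0.54 (permutation p = 0.00416) did not pass over 28 classes (adjusted p = 0.0582). In edgeR's test on cell counts the share of T_5_ProTreg changed by 0.30 log2 per doubling of size (adjusted p = 0.00616) and that of M_3 by -0.21 (adjusted p = 0.0581). All tests were two-sided.

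For T_5_ProTreg, r was 0.60 (permutation p = 0.00214) without the 2 libraries farthest from the median size, and rho was 0.60 (permutation p = 0.00233) but no longer passed over 28 classes. Its rho was 0.54 in libraries 1 to 22 (permutation p = 0.0160), 0.77 in the 6 sized libraries from 23 to 30 (exact permutation p = 0.103) and 0.59 within the sets (permutation p = 0.00254). For M_3, r was -0.37 (permutation p = 0.0748) without the 2 farthest libraries and rho was -0.48 (permutation p = 0.0175) and did not pass either, so both calls rest on them in part. Its rho was -0.39 in libraries 1 to 22 (permutation p = 0.0923), -0.49 in libraries 23 to 30 (exact permutation p = 0.356) and -0.44 within the sets (permutation p = 0.0286). M_3 no longer passed over 28 classes with size split at its median (adjusted p = 0.106), or without any of libraries 2, 6, 10, 11, 12, 16, 17, 20, 25, 26, 27, 28, 29 or 30, with rho from -0.57 to -0.52. T_5_ProTreg passed without each library in turn, but not with size split (adjusted p = 0.428). Neither class passed the adjustment over 28 classes within the sets (adjusted p = 0.0711 for T_5_ProTreg and 0.358 for M_3).

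**Figure D3:**
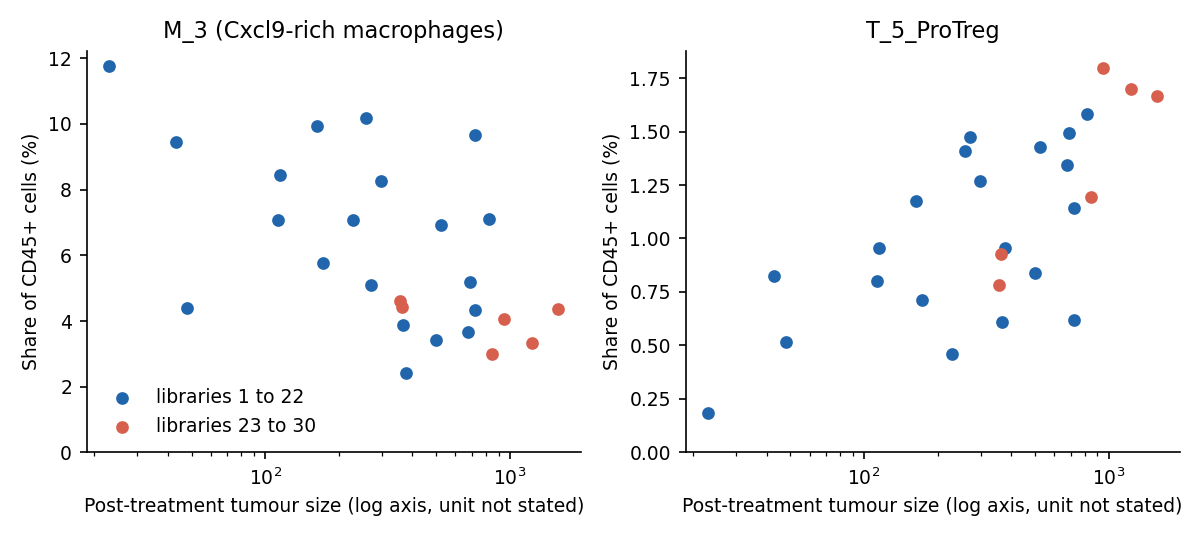
Share of M_3 (left) and of T_5_ProTreg (right) among annotated CD45+ cells (y axes, percent) against the size of the other tumour after treatment (x axes, log scale, unit not stated), 1 point per library, coloured by library set. M_3 ran from 2.43% to 11.8% and T_5_ProTreg from 0.183% to 1.80% in the 26 sized libraries.

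The other 26 classes did not pass. The undivided regulatory T cells of T_2_Treg made up 5.18% ± 1.75 of CD45+ cells (rho = 0.23, permutation p = 0.254, n = 26), T_1_CD8-4, named for CD8 and CD4 cells but led by the gamma delta T cell genes Trdv4 and Cd163l1, made up 8.69% ± 3.37 (rho = -0.04, permutation p = 0.861), and the dividing macrophages of M_7_Pro 2.81% ± 1.67 (rho = 0.22, permutation p = 0.276). Conventional dendritic cells of DC_1, with the cDC1 genes Xcr1 and Clec9a among their leading genes, made up 1.39% ± 0.77 (rho = 0.29, permutation p = 0.157). In libraries 1 to 22 rho of DC_1 was 0.47 (permutation p = 0.0380), in libraries 23 to 30 -0.37 (exact permutation p = 0.497) and within the sets 0.30 (permutation p = 0.139). Whole lineages did not vary with size either: T cells held 9.09% to 31.2% of CD45+ cells over 30 libraries (rho = -0.03, permutation p = 0.897) and NK cells 24.1% ± 7.79 (rho = -0.13, permutation p = 0.526). Cell number, depth, mitochondrial share and possible doublets per library had no detectable relation with size. Their rho values lay between -0.15 (mitochondrial share, permutation p = 0.455) and 0.07 (median UMIs, p = 0.739).

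Counted among myeloid cells alone, M_3 had the lowest p of the 15 classes, but it did not pass. It made up 11.2% ± 5.15 of the myeloid cells (n = 26, rho = -0.52, permutation p = 0.00815, adjusted p = 0.122 over 15 classes, r = -0.52, p = 0.00683). Without the 2 farthest libraries r was -0.38 (permutation p = 0.0635). Its rank correlation was -0.49 in libraries 1 to 22 (permutation p = 0.0307), 0.03 in libraries 23 to 30 (exact permutation p = 1.0) and -0.42 within the sets (permutation p = 0.0376). Monocytes of M_5_Mono made up 8.61% ± 3.67 (rho = -0.18, permutation p = 0.368) and the Arg1-rich M_6 6.16% ± 2.18 (rho = 0.06, permutation p = 0.753). M_1, the most numerous class, held 23.4% ± 5.66 (rho = 0.31, permutation p = 0.129).

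Cxcl9 itself was measured over all monocytes and macrophages, classes M_1 to M_9, without using their boundaries. Its level was 813 ± 415 CPM (SD, n = 26) and its relation with size did not pass by ranks (r = -0.41, permutation p = 0.0373; rho = -0.38, p = 0.0596, adjusted p = 0.0596 over 2 measures). With every cell thinned to 1000 UMIs, 27.6% ± 11.95 of the cells had a Cxcl9 UMI (r = -0.43, permutation p = 0.0294; rho = -0.41, p = 0.0424, adjusted p = 0.0596). Unthinned, the share was 47.5% ± 14.5 (rho = -0.49, permutation p = 0.0131). The background of this measure was low: 1.36% ± 1.10 of T cells and 0.45% ± 0.29 of NK cells had a Cxcl9 UMI after thinning (n = 30), with library median depths that averaged 10100 UMIs in macrophages, 5517 in T cells and 6059 in NK cells before it. The thinned share in NK cells had no detectable relation with size (rho = -0.29, permutation p = 0.154), but with 2000 UMIs per cell it did (rho = -0.49, permutation p = 0.0120), so free Cxcl9 RNA may follow size as well. No cell was left out by thinning, since the shallowest annotated cell had 2224 UMIs. Without the 2 farthest libraries r of the thinned share was -0.29 (permutation p = 0.175) and that of the level -0.29 (permutation p = 0.176), so both relations rest on those libraries. In libraries 1 to 22 rho of the thinned share was -0.41 (permutation p = 0.0739) and that of the level -0.37 (p = 0.107). In libraries 23 to 30 both were 0.09 (exact permutation p = 0.919), and within the sets they were -0.33 (permutation p = 0.106) and -0.30 (p = 0.151).

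The level inside M_3 did not vary with size, 2653 ± 459 CPM (rho = 0.09, permutation p = 0.662, n = 26). In the other monocytes and macrophages it was 518 ± 293 CPM (rho = -0.39, permutation p = 0.05005).

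**Figure D4:**
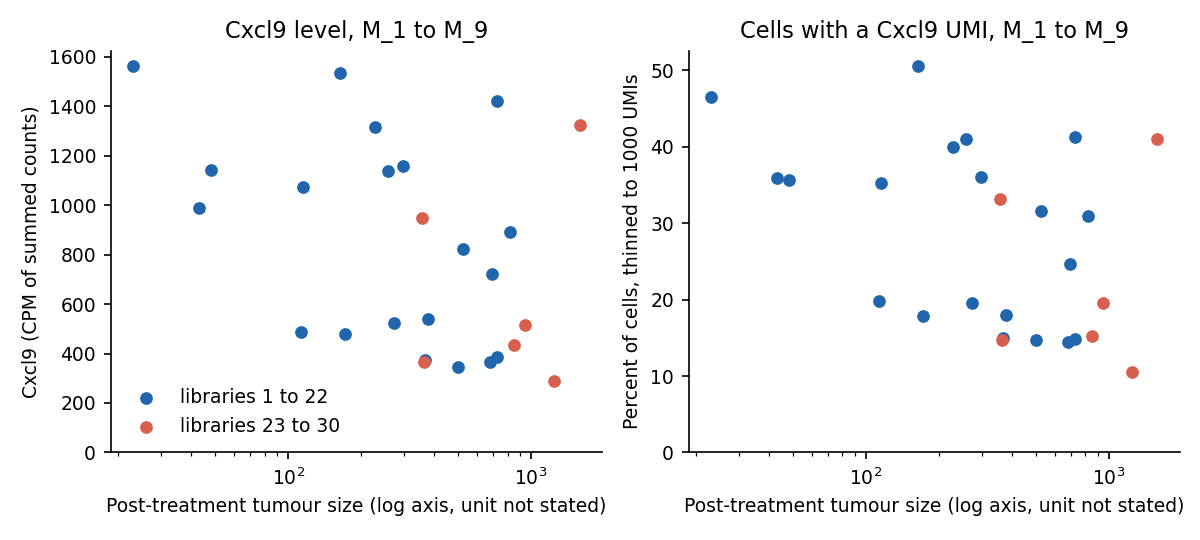
Cxcl9 level (left, CPM of summed counts) and percent of cells with a Cxcl9 UMI after thinning to 1000 UMIs (right) in classes M_1 to M_9, against the size of the other tumour (x axes, log scale, unit not stated), 1 point per library, coloured by library set. The level averages 813 CPM and the share 27.6% over the 26 sized libraries.

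No single gene of the monocytes and macrophages passed the test against size. edgeR called 0 of 12704 genes, with 1968 at an unadjusted p under 0.05, and DESeq2 called 25 higher and 23 lower. The genes nearest to the threshold, none of which passed in edgeR, were Nr1d1, a clock repressor, with a slope of 0.30 ± 0.06 log2 per doubling of size (SE, n = 26, adjusted p = 0.0672), the phosphodiesterase gene Pde2a (0.21 ± 0.04, adjusted p = 0.0876) and the leukotriene enzyme gene Alox5 (0.25 ± 0.05, adjusted p = 0.0961). On the other side stood the inhibitory receptor gene Cd300lf (-0.13 ± 0.02, edgeR adjusted p = 0.0672), Bambi (-0.14 ± 0.03) and the cytokine signalling brake Socs3 (-0.12 ± 0.02).

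Of the genes named in advance, Nos2 had the steepest slope, -0.53 ± 0.17 log2 per doubling at 26.1 ± 34.7 CPM (edgeR p = 0.00357, adjusted p = 0.162). Cxcl10 had -0.17 ± 0.06 at 505 ± 213 CPM, Cd274 -0.17 ± 0.07 at 137 ± 68.0 CPM, Cxcl9 -0.16 ± 0.08 and Arg1 -0.14 ± 0.07 at 1052 ± 435 CPM, with adjusted p from 0.233 to 0.338 in edgeR. Slopes of Spp1 (0.09 ± 0.08), C1qa (0.06 ± 0.04), Mrc1 (-0.003 ± 0.038), H2-Ab1 (-0.007 ± 0.045) and Ly6c2 (-0.07 ± 0.06) did not differ from 0. Ly6c2 has a close paralog, so its counts are uncertain. Cd274 lies on chromosome 19 (29367455 to 29388095, plus strand), Cxcl10 on chromosome 5 (92346638 to 92348889, minus strand) and Nos2 on chromosome 11 (78920787 to 78960254, plus strand).

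The genes that interferon-γ induces and those of hypoxia and glycolysis had lower slopes than other genes in the monocytes and macrophages, and cell cycle genes had higher ones. With camera and its preset correlation, 6 of 17 lists were called, and with the correlation estimated from the data none passed after adjustment in any cell set. The interferon-γ list had slopes below 0 in 28 of 28 genes, with a median of -0.16 log2 per doubling of size (camera adjusted p = 3.2e-13, p = 0.0903 with the estimated correlation). Socs1, which damps cytokine signals (-0.22 ± 0.06, SE), Nos2 (-0.53 ± 0.17) and the transcription factor gene Irf1 (-0.16 ± 0.05) passed when adjusted over the list alone, and no member passed over all genes. Hypoxia and glycolysis genes had slopes below 0 in 30 of 30, with 20 past the threshold adjusted over the list alone (camera adjusted p = 8.2e-13, p = 0.0681 with the estimated correlation). They were led by Pfkl (-0.15 ± 0.04), Pdk1 (-0.17 ± 0.05), P4ha1 (-0.08 ± 0.02) and Pfkfb3 (-0.13 ± 0.04). Cell cycle genes had slopes above 0 in 34 of 34 (camera adjusted p = 1.1e-15, p = 0.0780 with the estimated correlation), led by the replication genes Mcm5 (0.15 ± 0.05) and Tyms (0.18 ± 0.07), with 0 adjusted over the list alone and 14 at an unadjusted p under 0.05. The summed cells mix their classes. Without M_3 the interferon-γ list was still called lower (camera adjusted p = 3.8e-13, p = 0.0868 with the estimated correlation). Without M_7_Pro the cell cycle list was still called higher (camera adjusted p = 2.4e-13, p = 0.0376 with the estimated correlation). Other changes in the mix were not tested.

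The MHC class I list was also called lower (20 of 22 slopes below 0, camera adjusted p = 2.8e-05, p = 0.145 with the estimated correlation), with Tap1 (-0.12 ± 0.04) and Tap2 (-0.11 ± 0.05) first. The complement and lipid list was called higher (24 of 29 slopes above 0, camera adjusted p = 0.00327, p = 0.144 with the estimated correlation), with Ctsd (0.09 ± 0.03) and Adgre1 (0.08 ± 0.03) first. The ribosomal list, which follows RNA quality, was called higher too (20 of 21 slopes above 0, camera adjusted p = 0.00476, p = 0.360 with the estimated correlation). Its leading genes were Rpl32 (0.04 ± 0.02) and Rplp0 (0.03 ± 0.02). With the library set as a term the last 2 lists no longer passed (camera adjusted p = 0.312 and 0.424), and the inflammatory cytokine list was called lower (camera adjusted p = 0.000807, p = 0.0766 with the estimated correlation). Without that term the other lists did not pass in these cells: monocyte genes had an adjusted p of 0.116, inflammatory cytokines 0.226, regulatory T cell genes 0.226, MHC class II 0.230, alternative activation 0.238, type I interferon 0.374, cytotoxic genes 0.510, naive and memory T cell genes 0.510, checkpoint genes 0.678, mitochondrial genes 0.986 and dissociation stress 0.992. As many lists were called in 72 of 100 assignments of sizes to libraries, the real one included, with a median of 7 among the random ones. The number of lists called is therefore no evidence of a relation with size.

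**Figure D5:**
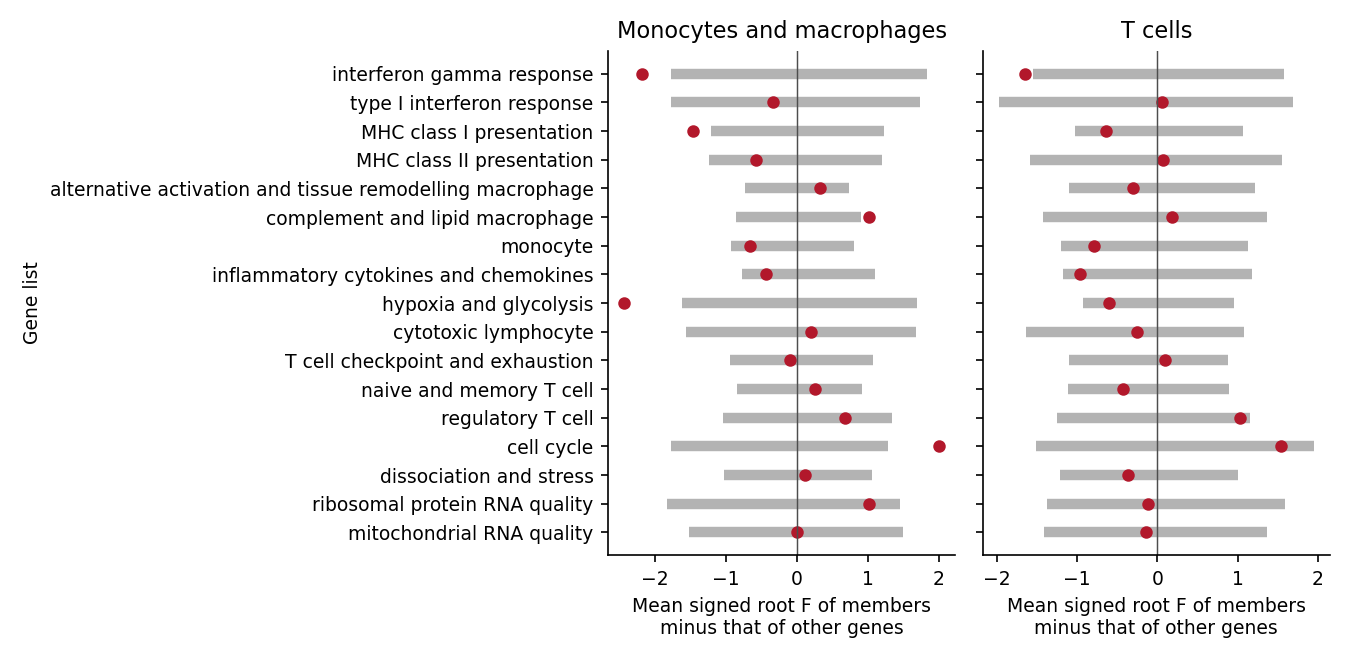
Shift of each gene list in monocytes and macrophages (left) and T cells (right) with tumour size (x axes, mean signed root F of members minus that of other genes), red dots for the real sizes and grey bars for the middle 95% of 99 random assignments of sizes. On the left, hypoxia and glycolysis stands at -2.43, interferon-γ at -2.18 and cell cycle at 2.01.

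In the T cells, 8 of 11213 genes passed (5 rose and 3 fell with size, edgeR), with 1345 at an unadjusted p under 0.05. DESeq2 called 57 higher and 63 lower. Myb, a transcription factor gene of progenitors, rose by 0.19 ± 0.04 log2 per doubling of size (SE, n = 26, edgeR adjusted p = 0.0441), Hacd3 by 0.11 ± 0.02 (adjusted p = 0.0441) and the nucleosome binding gene Hmgn5 by 0.12 ± 0.02 (adjusted p = 0.0499). Ahnak fell by 0.09 ± 0.02 and Rasgrp1, which links the T cell receptor to Ras, by 0.17 ± 0.03 (edgeR adjusted p = 0.0441 for both). The other genes called, all under 10 CPM and named after their values were seen, were Plpp1, Mgmt and Slc39a8. With the library set as a term edgeR called 0 genes (1161 at an unadjusted p under 0.05), and in libraries 1 to 22 alone 0 (1048).

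Of the T cell genes named in advance, Foxp3 had a slope of 0.10 ± 0.04 at 183 ± 40.5 CPM (edgeR p = 0.01004, adjusted p = 0.253), Pdcd1, which encodes the receptor PD-1, 0.09 ± 0.04 (adjusted p = 0.319) and Ifng -0.22 ± 0.11 at 183 ± 123 CPM (adjusted p = 0.393). Gzmb (0.0012 ± 0.0488), Prf1 (0.0082 ± 0.103) and Cd8a (-0.01 ± 0.06) did not differ from 0. Foxp3 lies on chromosome X (7573644 to 7595245, plus strand). The regulatory T cell list was called higher (16 of 22 slopes above 0, camera adjusted p = 0.0128, p = 0.227 with the estimated correlation), with Ikzf2 (0.11 ± 0.02) and Klrg1 (0.20 ± 0.06) past the threshold adjusted over the list alone. The interferon-γ list was called lower (25 of 26 slopes below 0, camera adjusted p = 2.5e-07, p = 0.0892 with the estimated correlation), with Icam1 (-0.14 ± 0.04) the only gene past the threshold adjusted over the list alone, ahead of Socs1 (-0.12 ± 0.04). The cell cycle list was called higher (33 of 34 slopes above 0, camera adjusted p = 1.8e-08, p = 0.166 with the estimated correlation), with Cenpa (0.10 ± 0.03), H2afz (0.11 ± 0.03) and Mcm6 (0.12 ± 0.03) past the threshold adjusted over the list alone. Summed T cells mix their classes, and the share of T_5_ProTreg rose with size. In libraries 1 to 22 the regulatory T cell list did not pass (camera adjusted p = 0.0924, p = 0.452 with the estimated correlation). As many lists were called in 92 of 100 assignments of sizes, the real one included.

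In all CD45+ cells together, 2 of 14680 genes passed in edgeR, both lower with size, with 1607 at an unadjusted p under 0.05. DESeq2 called 11 higher and 16 lower. These were the muscle genes Des (-0.64 ± 0.11 log2 per doubling, SE, adjusted p = 0.0415, edgeR) and Acta1 (-0.72 ± 0.13, adjusted p = 0.0415), at 0.21 ± 0.42 and 0.89 ± 2.47 CPM, named after their values were seen. Both rest on library 2, the library with the smallest size, without which Des had a slope of -0.27 and Acta1 of -0.16 in edgeR and neither passed. Of the genes above 10 CPM, none passed. The nearest were Hmgn2 (0.09 ± 0.02), Il10 (0.29 ± 0.08) and Tpm1 (0.08 ± 0.02) with positive slopes and Socs3 (-0.12 ± 0.02), B4galt3 (-0.12 ± 0.03) and Il4ra (-0.09 ± 0.02, edgeR adjusted p = 0.109) with negative ones.

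All CD45+ cells include the macrophages, so their lists are no separate test. The complement and lipid list and the ribosomal list were called only in macrophages, and the monocyte list only in all CD45+ cells. The interferon-γ list was lower (28 of 28 slopes below 0, camera adjusted p = 5.3e-19, p = 0.0285 with the estimated correlation), with 22 genes past the threshold adjusted over the list alone, led by Socs1 (-0.19 ± 0.05) and Nos2 (-0.58 ± 0.16). Hypoxia and glycolysis was lower (30 of 30 slopes below 0, camera adjusted p = 4.6e-14, p = 0.0291 with the estimated correlation), with 19 genes past the threshold adjusted over the list alone, led by Pfkl (-0.13 ± 0.03). MHC class I (camera adjusted p = 1.5e-05, p = 0.0554 with the estimated correlation), led by Tap2 (-0.10 ± 0.03) and Tap1 (-0.10 ± 0.03), had 4 genes past it adjusted over the list alone. Monocyte genes (camera adjusted p = 0.0121, p = 0.143 with the estimated correlation), led by Ly6i (-0.27 ± 0.09) and S100a4 (-0.16 ± 0.06), had 0. Cell cycle genes were higher (34 of 34 slopes above 0, camera adjusted p = 5.3e-17, p = 0.0388 with the estimated correlation), with Tyms (0.14 ± 0.04), Cenpa (0.10 ± 0.03) and Rrm1 (0.08 ± 0.03) past the threshold adjusted over the list alone. With the estimated correlation no list passed after adjustment (lowest adjusted p = 0.220). Monocyte genes also did not pass with the library set as a term (camera adjusted p = 0.129, p = 0.329 with the estimated correlation) or in libraries 1 to 22 (camera adjusted p = 0.352, p = 0.518 with the estimated correlation). As many lists were called in 86 of 100 assignments, the real one included.

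Fitted class by class, 33 calls fell in 10 of the 23 classes tested, and M_2, the macrophage class richest in the mannose receptor gene Mrc1 (1292 ± 249 CPM), held 15 of them out of 10073 genes. There the endothelin receptor gene Ednrb rose by 0.58 ± 0.09 log2 per doubling of size (SE, n = 26, edgeR adjusted p = 0.00326), the clock gene Nr1d1 by 0.31 ± 0.06 and Pde2a by 0.30 ± 0.06 (adjusted p = 0.0150 for both). Cd300lf fell by 0.27 ± 0.05 and the phosphatase gene Dusp16 by 0.16 ± 0.03 (edgeR adjusted p = 0.0150 for both), and Fbxl5, an iron sensor gene, by 0.20 ± 0.04 (adjusted p = 0.0204). M_4, the class richest in C1qa (4622 ± 763 CPM), had 6 calls of 10209: S100a8 fell by 0.43 ± 0.08, Trim35 by 0.12 ± 0.02 and Csf2rb2, a cytokine receptor gene with a close paralog and so with uncertain counts, by 0.18 ± 0.04 (edgeR adjusted p from 0.0426 to 0.0491). With the library set as a term edgeR called 0 genes in M_2 (772 at an unadjusted p under 0.05) and 6 in M_4, and within libraries 1 to 22 it called 0 in M_2 (950) and 0 in M_4 (979). DESeq2 called 70 in M_2 and 45 in M_4.

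S100a8, a neutrophil alarmin gene, also fell in M_8, by 0.75 ± 0.12 (n = 25, edgeR adjusted p = 0.00444) at 14.3 ± 25.5 CPM. Its level in the neutrophil-like class M_10 was 1840 ± 559 CPM (3 libraries). Socs3 fell in the dendritic cells of DC_2, by 0.16 ± 0.03 (adjusted p = 0.0136), and in M_5_Mono, by 0.16 ± 0.03 (edgeR adjusted p = 0.0361). DC_2 had 5 calls of 10093, all lower, among them the transcription factor gene Hhex (-0.29 ± 0.05, edgeR adjusted p = 0.0136) and Fcrlb (-0.29 ± 0.06, adjusted p = 0.0483). Single calls were Ndnl2 in DC_3 (0.20 ± 0.04, edgeR adjusted p = 0.0450), the sugar transporter gene Slc2a6 in M_3 (0.16 ± 0.03, adjusted p = 0.0487), Sclt1 in NK_3_Pro (-0.15 ± 0.03), S100a4 in NK_5 (-0.25 ± 0.05) and Il13 in T_2_Treg (-1.24 ± 0.20 at 7.23 ± 26.3 CPM, edgeR adjusted p = 0.0130). Il13 was named after its values were seen. With the library set as a term, S100a8 still passed in M_8 (edgeR adjusted p = 0.0126), while edgeR called 0 genes in DC_2, DC_3, M_3, M_5_Mono, NK_3_Pro, NK_5 and T_2_Treg, with 763, 541, 628, 583, 377, 314 and 687 at an unadjusted p under 0.05. DESeq2 called 241 genes over all 23 classes without that term.

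Where M_3 made up more of the myeloid cells, helper T cells were more frequent and cDC1 cells, dividing macrophages and M_1 macrophages less so, over all 30 libraries and 27 classes. DC_1 had a rho of -0.67 with the M_3 share (permutation p = 6.0e-05, adjusted p = 0.00162, r = -0.71 with p = 3.0e-05). T_3_CD4, with Il13, Csf2 and Ifng among its leading genes, had 0.66 (permutation p = 0.00018, adjusted p = 0.00243, r = 0.70 with p = 2.0e-05). M_7_Pro had -0.63 (permutation p = 0.00027, adjusted p = 0.00243, r = -0.63 with p = 0.00018) and M_1 -0.58 (permutation p = 0.00092, adjusted p = 0.00621, r = -0.54 with p = 0.00206). Without the 2 farthest libraries r was -0.64 for DC_1, 0.57 for T_3_CD4, -0.60 for M_7_Pro and -0.58 for M_1, with permutation p from 0.000200 to 0.00167.

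The same relations were read in each library set. In libraries 1 to 22 rho was -0.74 for DC_1 (permutation p = 0.00021), 0.83 for T_3_CD4 (p = 1.0e-05, the smallest these permutations can give), -0.65 for M_7_Pro and -0.52 for M_1. In the 8 libraries from 23 to 30 it was -0.33, 0.24, -0.71 and -0.83 (exact permutation p = 0.428, 0.582, 0.0576 and 0.0154). Within the sets it was -0.69, 0.71, -0.65 and -0.56 (permutation p from 3.0e-05 to 0.00170). Shares of 1 total push each other down, so the classes outside the myeloid table were also counted among themselves. T_3_CD4 kept a rho of 0.62 (permutation p = 0.00035, adjusted p = 0.00455 over 13 classes) and NK_4, with Gzmb and Gzma leading, had -0.57 (p = 0.00135, adjusted p = 0.00877). The shares of DC_1, M_7_Pro and M_1 lie in the same total as M_3, so a part of their fall with M_3 can come from the shared total alone.

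The summed T and NK cells carried more RNA of Pdcd1lg2, Gbp5 and other genes in libraries whose macrophages made more Cxcl9. The sum mixes classes whose shares outside the myeloid table went with that of M_3 (rho = 0.62 for T_3_CD4 and -0.57 for NK_4). A change in this mix and a change within cells are therefore not told apart here. Over 30 libraries, 9 genes rose and 8 fell with log2 Cxcl9 of the macrophages, of 12038 tested in edgeR, with 1373 at an unadjusted p under 0.05. DESeq2 called 39 higher and 58 lower. Pdcd1lg2, which encodes the PD-1 ligand PD-L2 (chromosome 19, 29410919 to 29471161, plus strand), rose by 0.20 ± 0.04 log2 per doubling of Cxcl9 (SE, edgeR adjusted p = 0.0165) at 126 ± 20.7 CPM. Abhd17c rose by 0.37 ± 0.07 (adjusted p = 0.0165), Serpina3g, a protease inhibitor gene, by 0.30 ± 0.06 (adjusted p = 0.0226) and the interferon-induced Gbp5 by 0.32 ± 0.06 (edgeR adjusted p = 0.0290). Satb1, a chromatin organiser gene, rose by 0.24 ± 0.05, the T cell surface gene Thy1 by 0.17 ± 0.03 and St6gal1 by 0.45 ± 0.09 (edgeR adjusted p = 0.0290 for each). Tsc22d1 fell by 0.22 ± 0.04 (adjusted p = 0.0289).

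Of the other falling genes, Gas6 (-1.06 ± 0.21 at 0.740 CPM), Fcrls (-1.25 ± 0.26) and Mgl2 (-1.13 ± 0.24) had little RNA in T and NK cells and much more in macrophages, with ratios of 69.7, 39.4 and 29.1. Rapsn had about as much in both (8.54 and 9.64 CPM, ratio 1.13). These genes lie outside the naming rule and were chosen after their values were seen. With a term for the macrophage RNA in T and NK cells, edgeR still called Pdcd1lg2, Abhd17c, Serpina3g, Gbp5, Thy1 and St6gal1, but of the falling genes only Irak3. This RNA fell with Cxcl9 (rho = -0.48 over 30 libraries), so the term cannot test whether macrophage RNA made a rise. With the macrophage RNA of the same library subtracted instead, edgeR called 7 higher and 3 lower when it was scaled by C1q and Apoe, and 2 higher and 3 lower when scaled by Cxcl9. Library 4, the smallest, weighed most: without it 168 genes were called. In libraries 1 to 22 edgeR called 2 genes.

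On this fit, in a step added after the data were seen, camera called 9 lists, and as many were called in 45 of 100 assignments, the real one included. With the estimated correlation no list passed after adjustment (lowest adjusted p = 0.220), and the p values given with it below are unadjusted. The interferon-γ list was higher (24 of 27 slopes above 0, camera adjusted p = 1.5e-10, p = 0.0259 with the estimated correlation), with 10 genes past the threshold adjusted over the list alone, Gbp5 among them. As written, this list includes Cxcl9, whose macrophage level is the measure here, and T and NK counts hold some macrophage RNA. A part of its rise may thus be built in, and the lists were not tested again with that RNA subtracted. The complement and lipid list was lower (26 of 28 slopes below 0, camera adjusted p = 4.1e-13, p = 0.0227 with the estimated correlation), with 18 genes past it adjusted over the list alone. These are macrophage genes in summed lymphocytes. The type I interferon list was called lower (30 of 32 slopes below 0, camera adjusted p = 7.0e-07, p = 0.221 with the estimated correlation), as were MHC class II (15 of 15 below 0, camera adjusted p = 1.4e-07, p = 0.0812 with the estimated correlation) and cell cycle genes (31 of 34 below 0, camera adjusted p = 1.3e-06, p = 0.234 with the estimated correlation). Alternative activation (camera adjusted p = 7.0e-07, p = 0.0574 with the estimated correlation) and dissociation stress (0.000768, p = 0.154) were also called lower, and hypoxia and glycolysis (camera adjusted p = 0.00179, p = 0.0786 with the estimated correlation) and cytotoxic genes (0.00460, p = 0.215) higher.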

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

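Chosen only after the result was seen were the test of the M_3 share within the library sets, the size term for the library sets, the macrophage RNA term for T and NK genes, the subtraction of that RNA and the slopes after it, and the random assignments of sizes for genes and lists of macrophages, T cells, all CD45+ cells, M_2 and M_4. Barcodes that the authors left without a class, which no comparison uses, carried immune RNA. Of these 3269 barcodes, 17.4% held UMIs of both a Cd3 gene and a C1q gene, against 5.76% of annotated cells, and their Cxcl9 level was 178 CPM. They stand here because a signal appears in data outside the comparisons, with no control samples to set it against. Of them, 2293 had more than 4999 genes.

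The share of M_3 was lower where the other tumour ended up larger. Within the library sets rho was -0.44 (permutation p = 0.0286), which argues against the sets as the whole cause. With depth per cell held it was -0.57 (permutation p = 0.00265) and without possible doublets -0.57 (permutation p = 0.00266). Depth and possible doublets had no detectable relation with size (rho = 0.07 and 0.04), so neither step could change rho much. That lack of relation, and not these steps, argues against them as the whole cause. Only doublets with Cd3 and C1q UMIs were covered. A biological link between Cxcl9 macrophages and the size of the other tumour is a hypothesis, since it was found and tested on the same data, and it did not pass over 28 classes within the sets. Tumour size at resection is not given in the sources used here and stays open.

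Many genes differed between libraries 1 to 22 and 23 to 30. In the 26 sized libraries 771 genes were called in all CD45+ cells without a size term and 455 with it, and in all 30 libraries 1599 without a depth term and 1900 with it, which argues against size or depth as the whole cause. Of 100 splits into 8 and 22 libraries, only the real one, picked by a scan, called as many genes (highest other 1197), so chance is excluded only in part. Why another split called 1197 genes was not tested. A difference in handling or batch stays open, since the labels record none, and no biological explanation was tested.

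T and NK cells had genes that went with macrophage Cxcl9. Of the 8 falling genes 1 was still called with macrophage RNA as a term, and their median slope went from -0.94 to -0.63 and their median level was 19.6 times higher in macrophages, so macrophage RNA in lymphocyte droplets may account for part of them, while Rapsn, with a ratio of 1.13, stays open. That term fell with Cxcl9 (rho = -0.48) and cannot test whether macrophage RNA made a rise, so this RNA was subtracted instead. The subtraction left 7 of the 9 rising genes called when scaled by C1q and Apoe and 2 when scaled by Cxcl9. With the Cxcl9 scaling Thy1 also lost its call (0.17 ± 0.03 before, 0.14 ± 0.04 after) with 0.084% of its RNA removed. All 9 kept at least 0.84 of their slope, at 3.4 SE or more from 0, and the most RNA, 11.6%, was removed from Serpina3g (0.30 ± 0.06 before, 0.25 ± 0.06 after), which argues against macrophage RNA as the whole rise and leaves a part open. Random assignments of Cxcl9 levels argue against chance (1 of 100 called as many, the real one with 17, highest other 1). They do not exclude it, since they ignore the library sets and 1 of 100 is the lowest possible share. The count also hung on single libraries, with 3 genes called without library 17 and 168 without library 4. What links the rising genes to macrophage Cxcl9 stays open, a change in the mix of T and NK classes included.

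Random assignments of sizes were also set against the other counts. For macrophage genes the count tests nothing, since edgeR called 0 and all 100 of 100 must call as many (highest other 4, DESeq2 48). The number at an unadjusted p under 0.05, 1968, was reached by 1 of 100, the real one, with 1533 as the highest other, but it was 1018 without library 2 and 1213 with the library set as a term. For all CD45+ cells (2 of 100 as many, real 2, highest other 2) and T cells (3 of 100, real 8, highest other 179) few assignments called as many genes. The number at an unadjusted p under 0.05 was reached by 7 and 6 of 100 (real 1607 and 1345, highest other 3350 and 2160). For M_2 (1 of 100, real 15, highest other 2) and M_4 (1 of 100, real 6, highest other 1) only the real one called as many, and 3 and 1 of 100 reached the other number. M_2 and M_4 had the most calls of the classes tested, and no other class was set against random assignments. The highest count over all classes was not taken in each assignment. The shares of M_2 and M_4 therefore cannot tell whether chance made their calls. For all CD45+ cells and T cells the shares argue against chance for the numbers called but do not exclude it. No share of these counts was adjusted over the tests, and 1 of 100 is the lowest a share can be. These assignments ignore the library sets, which overlap with size. With the set as a term edgeR called 0 in all CD45+ cells (1227 at an unadjusted p under 0.05, DESeq2 27 without the term), 0 in T cells (1161, DESeq2 120) and 0 in M_2 (772, DESeq2 70). The genes called before kept a median of 0.91, 0.85 and 0.93 of their slopes with SEs 1.10, 1.11 and 1.13 times as large (Myb 0.19 ± 0.04 and 0.16 ± 0.04, Ednrb 0.58 ± 0.09 and 0.57 ± 0.11), and Il10 in M_2 kept 0.44, so calls ended by smaller slopes and larger errors together and the sets stay open as a part of the source. In M_4 it called 6, of which S100a8 and, named after their values were seen, Timp1, Inhba and Ttll12 were called before, with slopes of -0.47, -0.40, -0.70 and 0.23 against -0.43, -0.35, -0.63 and 0.19 without the term, which argues against the sets as the source of these 4. The 2 genes of all CD45+ cells, Des and Acta1, had slopes of -0.27 and -0.16 without library 2 and did not pass. Why a random assignment called 179 T cell genes was not tested. For lists chance is not excluded in macrophages (72 of 100, real 6, highest other 12), T cells (92 of 100, real 3, highest other 14) or all CD45+ cells (86 of 100, real 5, highest other 14). Single lists went farther than every random assignment: hypoxia and glycolysis in macrophages (-2.43, highest other 2.04, 1 of 100, adjusted share 0.17) and in all CD45+ cells (-2.27, highest other 2.099) and interferon-γ in all CD45+ cells (-2.55, highest other 2.44, 1 of 100 and adjusted share 0.085 for both). So did hypoxia and glycolysis in M_4 (-3.35, highest other 2.04, adjusted share 0.1275) and in M_2 (-2.04, highest other 2.01, adjusted share 0.17). No share was under 0.05 after adjustment over 17 lists.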

How the results depend on the processing

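Alternatives that use library sets, the 2 farthest libraries, other macrophage sets or a macrophage RNA term or subtraction were chosen after the data were seen. No paired analysis was possible because each mouse gave 1 library. Leaving out cells under 1000 UMIs removed none, and leaving out libraries under 2000 annotated cells removed only library 4, which has no size. Where no reason is given, the cause was not tested. Of the answers to comparisons under alternatives fixed in advance, 34 kept their direction and side of the threshold, 19 gained a call or genes and 20 lost one, and of the values of named genes and classes 362, 44 and 71 did, with 4 reversed. Under added alternatives these numbers were 31, 6 and 28 with 3 reversed, and 207, 6 and 101 with 15 reversed.

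The 2 CD45+ classes past the threshold became 0 with size split at its median, 0 without the 2 farthest libraries, 1 in libraries 1 to 22 (DC_4_pDC), 0 in libraries 23 to 30, 0 within the sets and 1 by edgeR on cell counts (T_5_ProTreg). For M_3 the values were, in that order, -0.72 (difference in logit, adjusted p = 0.106), -0.48 (adjusted p = 0.246), -0.39 (0.369), -0.49 (exact, 0.937), -0.44 (0.358) and -0.21 (slope, 0.0581). For T_5_ProTreg the first 5 were 0.59 (adjusted p = 0.428), 0.60 (permutation p = 0.00233, not past the adjustment), 0.54 (adjusted p = 0.223), 0.77 (exact, 0.937) and 0.59 (0.0711). Smaller sets have fewer samples. In libraries 23 to 30 rho turned to -0.37 for DC_1, -0.37 for M_1, -0.20 for M_7_Pro, 0.49 for T_3_CD4, 0.029 for M_3 among myeloid cells, 0.086 for the Cxcl9 percent and 0.086 for its CPM, none past an exact permutation test. The myeloid classes past the threshold went from 0 to 1 with size split (M_3, -0.83) and to 1 as shares of all CD45+ cells (M_3, -0.57, adjusted p = 0.0408). The Cxcl9 percent gave -0.41 in libraries 1 to 22 and -0.33 within the sets.

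DESeq2 called 48 genes in macrophages (0 in edgeR, with 1968 at an unadjusted p under 0.05), 27 in all CD45+ cells (2), 120 in T cells (8), 97 with Cxcl9 (17), 35 in DC_2 (5), 70 in M_2 (15), 45 in M_4 (6) and 241 over all classes (33). With no filter on low counts edgeR called 11 in macrophages, 17 in all CD45+ cells, 15 in T cells, 30 in DC_2, 33 in M_4 and 192 over all classes. With untransformed size it called 1 in all CD45+ cells, 7 over all classes and 0 in T cells, DC_2, M_2 and M_4. With the library set as a term it called 0 in all CD45+ cells, 0 in T cells, 0 in DC_2, 0 in M_2, 8 over all classes and 37 with Cxcl9. In libraries 1 to 22 it called 0 in all CD45+ cells, 0 in T cells, 1 in DC_2, 0 in M_2, 0 in M_4, 6 over all classes and 2 with Cxcl9. All CD45+ cells gave 0 with depth as a covariate and 0 with size split. Macrophages gave 3 without M_7_Pro and 1 with M_5_Mono alone. The relation with Cxcl9 gave 6 with depth as a covariate, 10 without possible doublets, 34 with macrophage RNA as a term, 10 with it subtracted when scaled by markers, 5 when scaled by Cxcl9 and 168 without libraries under 2000 cells. With the estimated correlation 0 lists were called in macrophages (6), 0 in T cells (3), 0 in all CD45+ cells (5) and 0 in total (14). T cell lists became 8 with the set term and 7 in libraries 1 to 22. Classes related to M_3 went from 4 to 2 outside the myeloid table (T_3_CD4, and NK_4, which was not among the 4).

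Slopes that changed sign lay near 0 and none passed: Arg1 0.055 in M_5_Mono alone, Spp1 -0.0091 with the set term, Mrc1 0.0015 with depth, 0.0077 with the set term, 0.0021 without M_7_Pro and 0.015 in M_5_Mono, H2-Ab1 0.024 without M_3 and 0.092 in M_5_Mono, Ly6c2 0.0087 in M_5_Mono, Gzmb in T cells -0.0012 with DESeq2, -6.9e-05 with no filter, -0.0025 with the set term and -0.027 in libraries 1 to 22, Prf1 in T cells -0.0057 with untransformed size and Cd8a 0.0020 with the set term.

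Each library was also left out in turn for the class shares against size, for Cxcl9, and for genes of macrophages, all CD45+ cells and the relation with Cxcl9. This was not done for genes of T cells or of single classes, for the lists or for the relations with the M_3 share. How far those calls rest on 1 library was not tested. T_5_ProTreg passed each time (0.60 to 0.72). M_3 lay between -0.66 (without library 9) and -0.52 (without library 2) and did not pass without any of libraries 2, 6, 10, 11, 12, 16, 17, 20, 25, 26, 27, 28, 29 or 30, so 1 class passed instead of 2. Among myeloid cells M_3 lay between -0.61 and -0.46 and passed (1 class instead of 0) without library 9 (-0.58) or 26 (-0.61). The Cxcl9 percent lay between -0.54 (without 26) and -0.33 (without 2) and had p over 0.05 without 2, 6, 10, 11, 12, 15, 16, 17, 21, 25, 28 or 29. The Cxcl9 CPM lay between -0.51 and -0.30 and had p under 0.05 without 7 (-0.42), 9 (-0.46), 14 (-0.40) or 26 (-0.51). Macrophage genes numbered 0 to 21: 4 without 6, 2 without 8, 7 without 9, 4 without 13, 2 without 15, 21 without 26 and 2 without 27. All CD45+ cells gave 0 to 18: 18 without 15, and 0 without any of 1, 2, 3, 5, 8 to 12, 17 to 21 or 25 to 30. The relation with Cxcl9 gave 3 to 168: 7 without 2, 168 without 4, 8 without 10, 10 without 11, 6 without 13, 4 without 15, 3 without 17, 4 without 21, 7 without 26 and 11 without 27. Slopes that changed sign were Mrc1 (-0.036 to 0.016), H2-Ab1 (-0.023 to 0.0066) and Ly6c2 (-0.093 to 0.032). Depth limits the rarest classes most, and classes with fewer than 15 libraries of 20 cells were not tested for genes.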

Other observations

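Of the values here, the genes and classes were chosen after their values were seen. The small class DC_5_pDC (411 cells, 8 libraries with 20 or more) carried RNA of plasmacytoid dendritic cells and of regulatory T cells at the same time. Siglech, a receptor gene of plasmacytoid dendritic cells, was at 1247 ± 98.2 CPM (SD) against 1917 ± 203 CPM in DC_4_pDC, and Foxp3 at 248 ± 38.5 CPM against 513 ± 112 CPM in T_2_Treg. Cd3e, a subunit gene of the T cell receptor complex, was at 658 ± 114 CPM there, 1352 ± 262 CPM in T_2_Treg and 42.6 ± 31.4 CPM in DC_4_pDC. Whether these are pairs of cells in a droplet was not tested.

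In M_2 macrophages more genes went with size than the naming rule lists. The cytokine gene Il10 rose by 0.44 ± 0.09 log2 per doubling of size (SE, n = 26, edgeR adjusted p = 0.0204) at 58.2 ± 41.5 CPM, and Alox5 by 0.26 ± 0.05 (adjusted p = 0.0204). The collagenase gene Mmp13 fell by 0.51 ± 0.10 (edgeR adjusted p = 0.0204) and Socs2 by 0.30 ± 0.07 (adjusted p = 0.0443). With the library set as a term Il10 had a slope of 0.19 and an adjusted p of 0.352.

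In the 20 sized libraries from 1 to 22, plasmacytoid dendritic cells of DC_4_pDC rose with size (rho = 0.67, permutation p = 0.00159, r = 0.60 with p = 0.00488), while pooled over 26 libraries rho was 0.13 (permutation p = 0.526), without the 2 farthest libraries r was 0.09 (p = 0.686), and within the sets rho was 0.41 (p = 0.0384). In libraries 23 to 30 rho was -0.14 (exact permutation p = 0.803).

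The libraries without a size had M_3 shares of 2.08% (library 4), 2.69% (22), 2.67% (23) and 6.03% (24) of CD45+ cells and Cxcl9 levels of 154, 302, 672 and 514 CPM in macrophages. M_9 made up 8.44% of CD45+ cells in library 21. Rps27rt, a near copy of a ribosomal protein gene, was at 561 CPM in library 4 and 271 CPM in library 10, the next highest, and went down with the number of annotated cells over 30 libraries (rho = -0.61, permutation p = 0.00051, r = -0.77 with p = 1.0e-05, the smallest these permutations can give, and -0.73 without the 2 farthest libraries). Gm10076, Gm10263 and Wdr89 were also highest in library 4 (452, 23.5 and 173 CPM).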
